A study of Mus musculus with 9 samples.

How the data were processed

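RNA was measured by bulk sequencing of total RNA from mouse cerebellum, in 9 libraries: 3 control (saline), 3 of mice given 3-acetylpyridine (3AP) and 3 of mice given PLX3397 and 3-acetylpyridine (PLX3AP), grouped as the labels give them. The deposited files are 18, a file of expected counts and a file of TPM for each library, with 55808 rows each. Per the submitters' processing notes, the authors used fastp, HISAT2, StringTie and RSEM on the mm10 build. Versions, the annotation release, the strandedness and any filter are not given in the sources used here. The deposited count files hold expected counts, that is reads estimated per gene and not normalised: 28.7 to 30.8% of their values above 0 are not whole. The deposited TPM files hold TPM, scaled to transcript length and library total by the authors, and each sums to between 999999 and 1000001. CPM (counts scaled to library size) and log2 fold changes were computed here from the deposited expected counts, and are not in the authors' files.

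Rows without a gene name (1884, with 0.526 to 0.660% of the counts) were left out of the comparisons, and of the rows with a name (53924), 1705 share 108 symbols and were kept apart. Ddit3 has 2 rows. Libraries held 18452256 to 22358447 estimated counts and 21643 to 22776 rows above 0. Rows of the 20 highest took 6.89 to 9.50% of the counts, and mitochondrially encoded genes 2.86 to 5.24%. Within groups the Pearson correlation of log2 CPM across genes was 0.980 to 0.988, where genes are not independent replicates, and the chi-square per degree of freedom 4.93 to 29.4, so that no pair agreed within sampling noise. Estimated counts divide reads shared between paralogs, so single members of close families (Ifit3 and Ifit3b, Ly6a and Ly6c1, H2-K1 and H2-D1, Ms4a6c and Ms4a6d, Lyz1 and Lyz2, the C4 and C1r genes, the haemoglobins, and mitochondrial genes with nuclear copies) are less certain than others. Counting intervals (95%, exact binomial) and floors (3 counts over the group) cover counting error only. A fold given as at least a value sets the floor for the group with 0 counts and takes the higher count as exact. It leaves out counting error in that higher count.

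Rounded expected counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr left 16634 genes, libraries were scaled by TMM (factors 0.986 to 1.02), and a quasi-likelihood model with robust dispersion and 1 term per group was fitted to all 9 libraries (biological coefficient of variation 0.126). The 3 contrasts were 3AP against control, PLX3AP against 3AP and PLX3AP against control. P-values are two-sided and adjusted by Benjamini-Hochberg over all tested genes of a comparison, with calls at an adjusted p under 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic. Means and SDs are of TMM-scaled CPM, and fold changes are those of the fit. Data were simulated from gene means and dispersions of all 9 libraries together. For each comparison, fold changes of 1.5, 2 and 4 were planted in 67, 67 and 66 genes. The fit recovered 52.2, 76.1 and 84.8% (3AP against control), 53.7, 80.6 and 92.4% (PLX3AP against 3AP) and 55.2, 65.7 and 86.4% (PLX3AP against control). Of the calls 12 of 154, 18 of 169 and 8 of 146 were false, each a share above 0.05.

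Gene lists were written down, with the comparisons, the tests, the alternatives and the rule for named genes, before the data were examined. The 32 lists (518 genes, 473 tested) cover the cell types of the cerebellum and its surroundings (homeostatic and disease-associated microglia, border-associated macrophages, blood leukocytes, erythroid cells, astrocytes and Bergmann glia, mature oligodendrocytes, oligodendrocyte precursors, Purkinje cells, granule cells, interneurons, endothelial and mural cells, meningeal fibroblasts, choroid plexus, hindbrain outside the cerebellum). They also cover pathways (cytokines and NF-kB signalling, type I interferon response, complement, antigen presentation, reactive astrocytes, phagocytosis and Fc receptors, immediate early genes, neuronal excitability channels, glutamatergic synapse, p53 targets, integrated stress response, NAD metabolism, oxidative phosphorylation, mitochondrially encoded genes, cell proliferation, cholesterol synthesis). Each was tested in each comparison with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 96 tests, beside camera with an estimated correlation and fry. Of the 48 list tests that passed, 20 also passed with an estimated correlation and 28 did not. With so low a preset correlation, genes of a list that change together can make p-values too small. Where only the preset p-value is printed for a list that passed with all libraries, it also passed with an estimated correlation. Fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, passed 35.

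Named genes were, per comparison, the 6 called higher and the 6 called lower with the smallest p among those with a mean of 1 CPM or more in a group, no overlap between groups and a symbol that is not a predicted-gene name; up to 4 called genes with the smallest p from each list, or where none was called the gene with the smallest p; and always Csf1r, Aif1, Tmem119, P2ry12, Cx3cr1, Itgam, Csf1, Il34, Tnf, Il1b, Calb1, Pcp2 and Gfap. Other members of a list are named where they complete a count. Some genes that the rule or a count would name are not reported here. Genes outside this rule are said to have been chosen after their values were seen. Positions are from GENCODE M21 on GRCm38 (mm10).

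For changes that moved back, called genes were counted and fold changes correlated beside 20 negative binomial simulations of unchanged groups that share libraries as the real comparisons do. Alternatives planned beforehand were RLE scaling, no TMM, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, the 6 libraries compared alone, a block by replicate number, an absolute log2 fold change of 1 or more, a fit without robust dispersion, limma-trend on the deposited TPM with 1 or 0.1 added before the log2, an estimated correlation and fry for the lists, and leaving out each library. Alternatives chosen after seeing the data were the log2 CPM of Ttr as a covariate, and offsets from a local regression on GC content and gene length. The value regressed was each library's log2 CPM relative to the mean of all libraries. GC content and gene length are, throughout, those of the longest annotated transcript of a gene (97.8% of tested genes have a GC content). All 10 splits of the 6 libraries of a comparison into groups of 3 were fitted. Permutation tests used 1e+05 resamples, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 made tables and figures. The raw reads were not analysed here, and no test of strandedness was made.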

Results

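Bulk RNA sequencing measured gene expression in the cerebellum of mice, in 9 libraries that fall into 3 groups of 3. The control mice had received saline. The 3AP mice had received 3-acetylpyridine (3-AP), a nicotinamide analogue that destroys neurons of the inferior olive, whose climbing fibres end on Purkinje cells, and that is used to cause ataxia. The PLX3AP mice had received 3-AP after treatment with PLX3397. PLX3397 inhibits the CSF1 receptor, on which microglia and many tissue macrophages depend, and is used to deplete them. A group with PLX3397 alone was not analysed here, so these comparisons do not give its effect without 3-AP. Library totals ran from 18452256 to 22358447 estimated counts, and 16634 genes had enough counts to test. The first principal component held 33.4% of the variance and set the 3AP libraries (33.2 to 42.6) apart from the 6 others (-25.9 to -14.2). Within groups, libraries differed by more than sampling noise (chi-square per degree of freedom of 4.93 or more in every pair). Xist had at most 3 counts in any library and the Y-linked gene Ddx3y at least 740, as in male tissue. Ttr, the main secreted product of the choroid plexus, ranged from 11.5 to 3813 CPM (counts scaled to library size, as throughout) between libraries, and it varied within each group. The labels do not say that each library came from its own animal. P-values of single genes and of fry therefore measure the spread between these samples, which may be technical. Camera also sets the genes of a list against other genes, and the permutation tests only shuffle genes between lists. Genes are not independent replicates, so those p-values do not measure a spread between animals either.

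**Figure D1:**
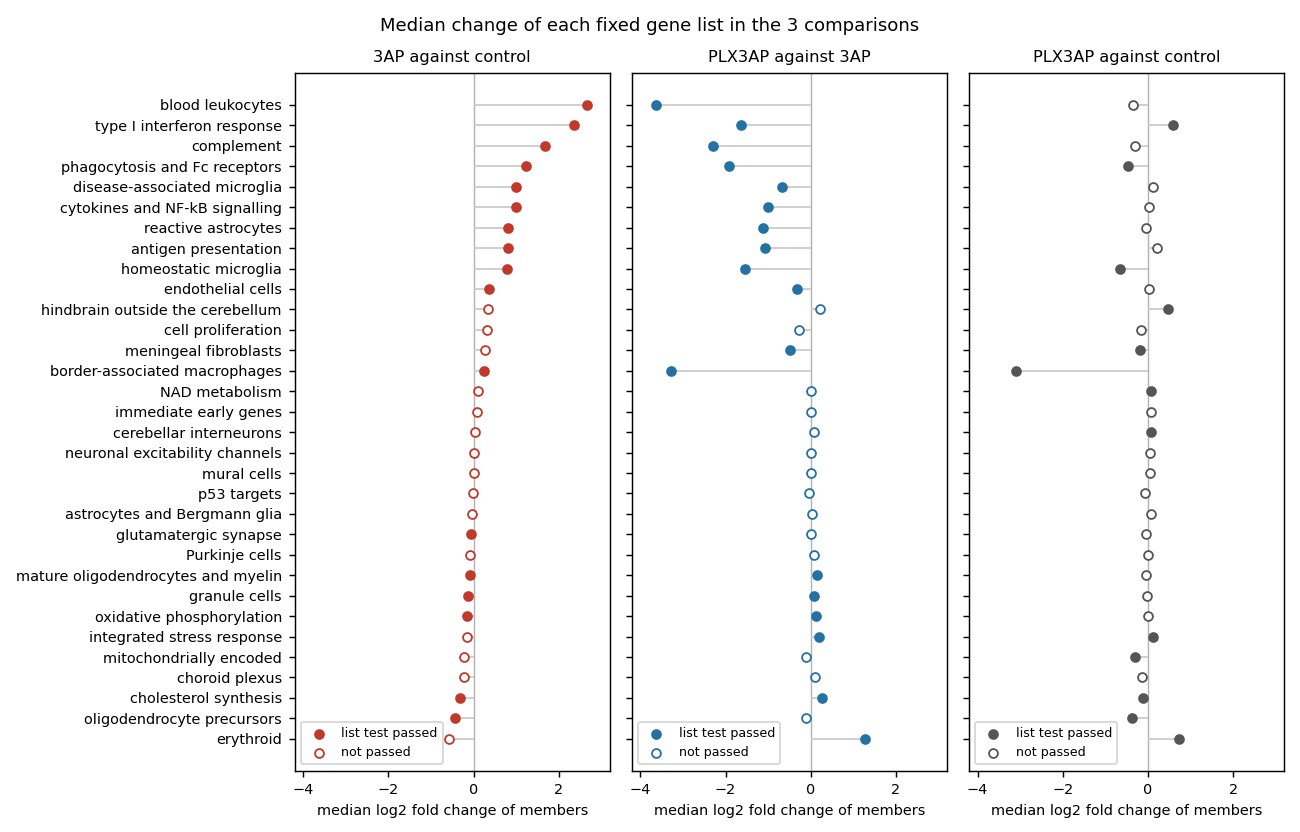
Median log2 fold change of each gene list fixed beforehand, in the 3 comparisons, with 3 libraries per group. Points are list medians (x axis, log2), filled where the list passed camera. The type I interferon list lies at 2.35 in 3AP against control and at -1.65 in PLX3AP against 3AP, and the border-associated macrophage list at -3.10 in PLX3AP against control.

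The comparison of 3AP with control asks what 3-AP changed in the cerebellum. After 3-AP, genes of the type I interferon response, antigen presentation, complement, phagocytosis, and cytokines and NF-kB signalling rose, and genes of cholesterol synthesis and oligodendrocyte precursors fell. Irf7, a transcription factor that drives type I interferon genes, rose 10.3-fold (log2 fold change 3.36, SE 0.15, 3 libraries per group), from 3.08 ± 0.358 CPM (mean ± SD) in control to 31.8 ± 5.23 in 3AP, with an edgeR adjusted p of 4.1e-07. Lcn2, an iron-binding protein secreted by reactive astrocytes and neutrophils, rose 157-fold, from 0.564 ± 0.247 to 89.6 ± 33.1 CPM (log2 fold change 7.30, SE 0.40, n = 3, edgeR adjusted p 2.9e-05). Gpr17, a marker of oligodendrocyte precursors about to differentiate, was 3.45-fold lower, at 24.4 ± 1.96 CPM in control and 7.08 ± 1.63 in 3AP (log2 fold change -1.79, SE 0.18, n = 3, edgeR adjusted p 9.0e-05).

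The type I interferon list had a median of 2.35. Its camera adjusted p was 3.6e-110 at the preset correlation and 0.0043 with an estimated correlation, and its fry adjusted p 0.00013. Of its 26 genes 25 rose and Ifit2 did not pass (26 adjusted over the list alone). Besides Irf7 these included Oasl2, a 2'-5' oligoadenylate synthetase-like protein (6.49-fold, log2 2.70, SE 0.17), Isg15, a ubiquitin-like modifier (6.38-fold, log2 2.67, SE 0.19), and Ifit3, which restrains viral RNA (3.42-fold, log2 1.77, SE 0.11). In antigen presentation 9 of 15 genes rose (10 higher and 2 lower adjusted over the list alone; median 0.80, camera adjusted p 3.9e-18). All 9 belong to the class I pathway: B2m, the light chain of class I molecules, rose 2.65-fold (85.0 ± 8.21 to 225 ± 18.1 CPM), H2-K1, a heavy chain, 3.82-fold, and Psmb8, a subunit of the immunoproteasome, 5.74-fold. The class II genes H2-Aa, H2-Ab1, H2-Eb1, Cd74, Ciita and H2-DMa did not pass.

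Complement genes rose in 13 of 15 cases (15 adjusted over the list alone; median 1.67, camera adjusted p 1.2e-38). C1qa, a chain of the initiating complex, went from 16.7 ± 1.65 to 51.8 ± 8.03 CPM (3.10-fold), and Itgb2, a chain of complement receptor 3, rose 4.56-fold. In the list of phagocytosis and Fc receptors 14 of 20 genes rose (16 adjusted over the list alone; median 1.24, camera adjusted p 1.4e-23), among them the antibody receptors Fcgr3 (3.2-fold, log2 1.68, SE 0.17) and Fcgr2b (7.63-fold, log2 2.93, SE 0.34). Among 18 markers of homeostatic microglia 9 rose (14 higher and 1 lower adjusted over the list alone; median 0.78), with a camera adjusted p of 2.1e-14 and adjusted p = 0.10 with an estimated correlation. Itgam, the other chain of complement receptor 3, rose 4.23-fold (6.73 ± 1.19 to 28.5 ± 7.06 CPM), Cx3cr1, the fractalkine receptor, 2.17-fold, Aif1, the microglial protein Iba1, 3.86-fold, and Ctss, a lysosomal protease, 2.47-fold. Tmem119, a microglial membrane protein, rose 1.78-fold (adjusted p 0.028), a call that was lost without control replicate 1 (0.135), control replicate 2 (0.112) or 3AP replicate 1 (0.149). Csf1r, the receptor that PLX3397 inhibits, was at 33.6 ± 1.39 CPM in control and 54.4 ± 5.57 in 3AP and did not pass with edgeR (log2 fold change 0.69, SE 0.18, adjusted p 0.054). P2ry12, a purinergic receptor of resting microglia, was at 9.61 ± 1.68 and 6.94 ± 1.86 CPM (log2 fold change -0.47, SE 0.25, edgeR adjusted p 0.39). Of the genes for the ligands of the CSF1 receptor, Csf1 rose 1.65-fold (19.6 ± 2.04 to 32.2 ± 3.48 CPM), and Il34, at 10.3 ± 1.79 and 8.74 ± 1.20 CPM, did not pass. Of 22 genes tested for disease-associated microglia 12 rose (14 adjusted over the list alone; median 1.00, camera adjusted p 6.0e-16, adjusted p = 0.067 with an estimated correlation), including Gpnmb (4.62-fold), Lyz2 (3.95-fold) and Ch25h, which makes 25-hydroxycholesterol (12-fold).

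In the list of cytokines and NF-kB signalling 11 of 24 tested genes rose (19 adjusted over the list alone; median 1.00, camera adjusted p 1.4e-21). The chemokine gene Ccl12 rose 19.3-fold (log2 4.27, SE 0.37), and Ccl5 had 3 counts over the control libraries and 716 over the 3AP libraries, a ratio of 240 with a 95% counting interval of 81.7 to 1166. Icam1, which binds leukocytes to endothelium, rose 8.27-fold and Ptgs2, the inducible cyclooxygenase, 6.76-fold. Il1b rose from 6 to 51 counts over the 3 libraries (edgeR adjusted p 0.041). The call was lost when any 1 of the 6 libraries was left out (control replicates 1, 2 and 3 and 3AP replicates 1, 2 and 3), with adjusted p of 0.061 to 0.16. Tnf, too low to test, had 0 counts in control and 11 in 3AP. With the 11 taken as exact, it was at least 3.69-fold higher against a floor of 3 counts over the group. Among the reactive astrocyte genes 8 of 19 rose (12 adjusted over the list alone; median 0.81, camera adjusted p 7.5e-22, adjusted p = 0.067 with an estimated correlation). Besides Lcn2 they included Timp1, an inhibitor of metalloproteinases (34.7-fold, log2 5.12, SE 0.47), and Cp, a copper-carrying ferroxidase (3.61-fold). Gfap, the astrocyte filament protein, rose 3.53-fold, from 220 ± 20.6 to 778 ± 334 CPM (edgeR adjusted p 0.013), and its adjusted p was 0.069 without control replicate 1, 0.060 without control replicate 2 and 0.054 without control replicate 3. Markers of blood leukocytes moved with these groups. Of 18 genes 7 could be tested, and 4 rose (7 adjusted over the list alone; median 2.67, camera adjusted p 1.8e-09, adjusted p = 0.053 with an estimated correlation). Plac8 was at 0.0984 ± 0.128 and 2.41 ± 0.706 CPM. The calls of Ly6c2 and Retnlg were lost without control replicates 1 or 2 or 3AP replicates 1 or 2 (adjusted p of 0.071 to 0.093 and of 0.092 to 0.18), and that of S100a9 without control replicate 2 (0.062). Endothelial genes also moved, with 6 of 12 higher and 2 lower (7 and 2 adjusted over the list alone; median 0.37, camera adjusted p 8.3e-06). The junction genes Cldn5 and Pecam1 rose 2.56-fold and 2.40-fold, Ly6c1 rose 2.06-fold, and Itm2a was 2.06-fold lower. Ly6a (Sca-1) rose 3.66-fold and Cd93, an endothelial and myeloid receptor, 4.21-fold. Of 10 genes of border-associated macrophages 3 rose (3 adjusted over the list alone; median 0.24), F13a1, Ms4a6c and Stab1. That list had a camera adjusted p of 0.024, and adjusted p = 0.51 with an estimated correlation. The call was lost without control replicate 2 (0.057), and the call of Stab1 (adjusted p 0.022) was lost without control replicates 1 or 2 or 3AP replicates 1 or 2 (0.088 to 0.11).

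Among the genes that fell with the smallest p were Tnc, Ltbp4, Itm2a, Ednrb and Gpr17. Tnc, a matrix glycoprotein made by astrocytes, went from 23.2 ± 1.62 to 8.69 ± 0.192 CPM (log2 -1.41, SE 0.12, edgeR adjusted p 2.9e-05). Ltbp4, which anchors latent TGF-beta, went from 34.5 ± 3.7 to 13.5 ± 1.36, and Ednrb, an endothelin receptor gene, from 130 ± 6.64 to 75.1 ± 5.79. Genes of cholesterol synthesis fell in 8 of 15 cases (12 adjusted over the list alone; median -0.32, camera adjusted p 1.9e-14). Hmgcs1 went from 170 ± 11 to 107 ± 7.42 CPM, Cyp51 from 65.8 ± 2.48 to 41.7 ± 1.29. Msmo1 went from 47.2 ± 3.51 to 30.4 ± 1.00 and Sqle from 41.1 ± 2.13 to 27.9 ± 2.30. Among 11 genes of oligodendrocyte precursors 3 fell (5 adjusted over the list alone; median -0.43, camera adjusted p 1.5e-07). These were Gpr17, Cacng4 (40.3 ± 3.86 to 24.3 ± 2.95 CPM) and Vcan, whose adjusted p of 0.016 rose to 0.069 to 0.087 without control replicates 1 or 2 or 3AP replicates 1 or 2. In the myelin list 2 of 15 fell (5 adjusted over the list alone; median -0.08, camera adjusted p 0.0022, adjusted p = 0.49 with an estimated correlation). These were Opalin, from 16.8 ± 1.07 to 8.62 ± 1.75 CPM, and Ugt8a, whose adjusted p of 0.012 became 0.055 to 0.069 without control replicate 1 or 3AP replicates 1 or 2. Of 15 astrocyte and Bergmann glia genes 3 fell (2 higher and 3 lower adjusted over the list alone) with a median of -0.03 and a camera adjusted p of 0.24. They were the transcriptional cofactor gene Hopx (170 ± 10.5 to 101 ± 12.4 CPM), the serine transporter gene Slc7a10 (43.0 ± 7.76 to 26.6 ± 1.13) and the water channel gene Aqp4. The adjusted p of Aqp4, 0.030, became 0.061 to 0.14 without control replicates 1 or 2 or 3AP replicates 1, 2 or 3.

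Medians of the neuronal lists lay between -0.14 and 0.04. The granule cell list had a median of -0.14 (camera adjusted p 0.0014, adjusted p = 0.30 with an estimated correlation), with 1 of 15 genes lower (2 adjusted over the list alone), Calb2, whose adjusted p of 0.010 was 0.068 without 3AP replicate 1. The glutamatergic synapse list had a median of -0.07 (camera adjusted p 0.020, adjusted p = 0.46 with an estimated correlation, and 0.090 without control replicate 1), and 1 of its 20 genes was called lower (4 adjusted over the list alone), Grik1. Its adjusted p of 0.025 became 0.069 to 0.13 without control replicates 1 or 2 or 3AP replicates 1 or 3. Oxidative phosphorylation genes had a median of -0.15 (camera adjusted p 0.00064, adjusted p = 0.57 with an estimated correlation); edgeR called 0 of 17, 5 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Purkinje cell genes had a median of -0.08 and did not pass (camera adjusted p 0.069), although the adjusted p was 0.013 without control replicate 3 and 0.0016 without 3AP replicate 2. Among them Calb1 was at 1254 ± 101 and 1106 ± 21.1 CPM (log2 fold change -0.18, SE 0.10) and Pcp2 at 432 ± 45.3 and 439 ± 52.6 (0.02, SE 0.10). EdgeR called 0 of 19 genes, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The other lists did not pass with camera. They were interneurons (median 0.04, adjusted p 0.92), neuronal excitability channels (0.02, 0.72), immediate early genes (0.07, 0.93), hindbrain outside the cerebellum (0.34, 0.53, 4 of 16 genes tested), and p53 targets (-0.01, 0.78). They also included integrated stress response (-0.15, 0.10), NAD metabolism (0.11, 0.21), mitochondrially encoded genes (-0.22, 0.22), and cell proliferation (0.31, 0.19), and the lists of erythroid genes (-0.57, 0.16), choroid plexus (-0.23, 0.90), meningeal fibroblasts (0.27, 0.19) and mural cells (0.01, 0.95). Single genes passed in 3 of these: Dcn, a collagen-binding proteoglycan, rose 2.57-fold and Bst1, an ectoenzyme that uses NAD, rose from 0.0662 ± 0.0748 to 1.47 ± 0.713 CPM. Phgdh, which opens serine synthesis, fell from 79.2 ± 5.29 to 55.6 ± 1.68 CPM. Slc7a5, an amino acid transporter, was called lower (adjusted p 0.036), a call lost when any 1 of the 6 libraries was left out (control replicates 1, 2 and 3 and 3AP replicates 1, 2 and 3; 0.062 to 0.14). Without control replicate 1 the erythroid list (0.030) passed, without control replicate 1 or 3AP replicate 1 the stress response list (0.028 to 0.029), and without control replicate 3 or 3AP replicate 3 the meningeal list (0.042). The median, mean and test of the mural, immediate early, excitability and p53 lists differed in sign.

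In all, edgeR called 820 of 16634 genes (Benjamini-Hochberg adjusted), 623 higher (76.0%) and 197 lower, with changes of 2-fold or more in 378 and 25. In each of the 820 the 3 values of 1 group lay beyond those of the other, which 24.7% of all tested genes also showed and 10% would by chance. The count was 487 without control replicate 1, 515 without control replicate 2, 466 without 3AP replicate 1 and 504 without 3AP replicate 2. From the authors' TPM, which also scale to transcript length, limma-trend called 482 or 416, and with a correction for GC content and gene length, chosen after seeing the data, edgeR called 1320. Of these 876 (66.4%) were higher and 444 lower. The 197 lower became 68 or 64 with limma-trend on TPM, 100 without control replicate 1 and 111 without control replicate 2. Without 3AP replicate 1 they became 85, and without 3AP replicate 2 they became 94. In GRCm38 (mm10) coordinates Irf7 lies on chromosome 7 from 141262706 to 141266481, Lcn2 on chromosome 2 from 32384633 to 32388252, Gpr17 on chromosome 18 from 31942997 to 31949636 and Tnc on chromosome 4 from 63959785 to 64047015.

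**Figure D2:**
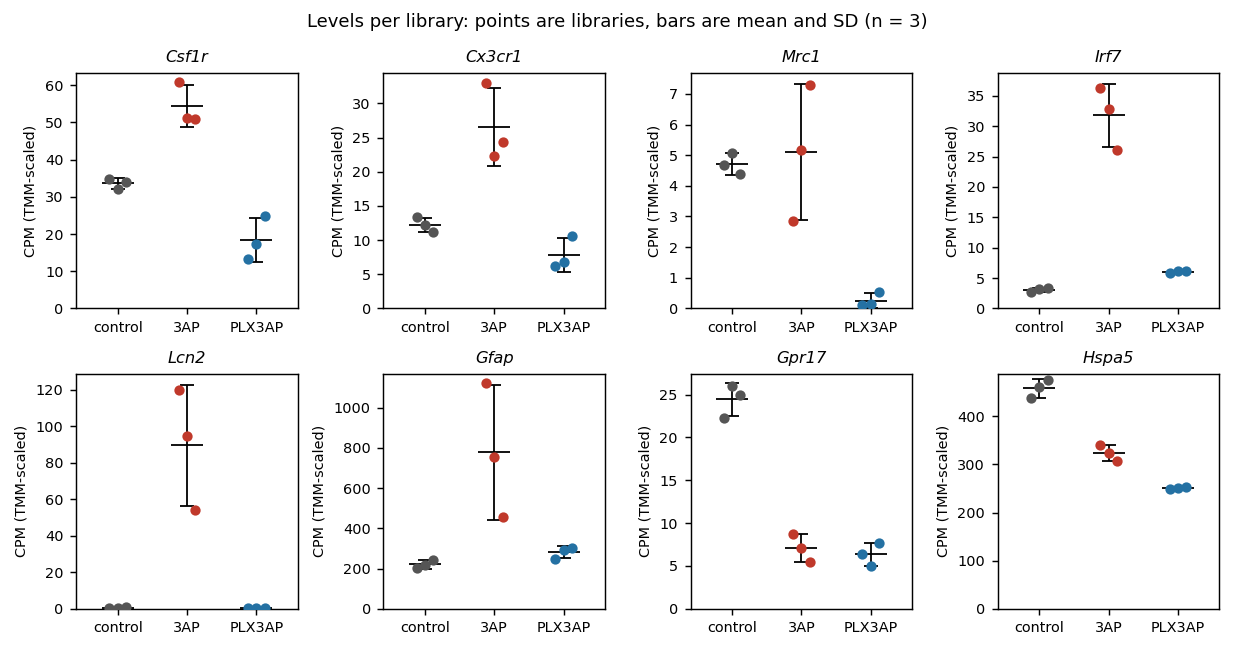
Levels of 8 genes in each library, in CPM (y axes), by group, with bars for the mean and SD of the 3 libraries. Irf7 and Lcn2 lie far higher in the 3AP libraries (means of 31.8 and 89.6 CPM) than in the others, and Mrc1 is near 0 in the PLX3AP libraries (0.257 ± 0.233).

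The comparison of PLX3AP with 3AP asks what treatment with PLX3397, given to deplete microglia, changed in mice that received 3-AP. Markers of microglia and of border-associated macrophages fell, and with them interferon, complement, phagocytosis, cytokine and NF-kB signalling, and antigen presentation genes, which had been higher in 3AP than in control. Csf1r fell from 54.4 ± 5.57 CPM in 3AP to 18.5 ± 5.92 in PLX3AP (log2 fold change -1.55, SE 0.18, n = 3, edgeR adjusted p 0.00069). F13a1, a coagulation factor subunit made by macrophages, was 27.8-fold lower (log2 -4.80, SE 0.35, n = 3, edgeR adjusted p 1.6e-05). Irf7 was 5.27-fold lower (log2 -2.40, SE 0.14, n = 3, edgeR adjusted p 8.9e-06), and Lcn2 201-fold lower, at 0.438 ± 0.048 CPM in PLX3AP (log2 -7.65, SE 0.41, n = 3, edgeR adjusted p 3.6e-05).

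Of the 18 homeostatic microglia markers 12 fell (15 adjusted over the list alone). The list median was -1.53, with a camera adjusted p of 6.8e-49, 0.011 with an estimated correlation, and a fry adjusted p of 0.00059. Itgam was 6.85-fold lower (28.5 ± 7.06 to 4.14 ± 1.29 CPM), Aif1 5.86-fold, Ctss 3.89-fold, Cx3cr1 3.38-fold and Tmem119 2.86-fold. P2ry12 was at 6.94 ± 1.86 and 3.81 ± 1.29 CPM and did not pass with edgeR (log2 -0.87, SE 0.27, adjusted p 0.13). Among border-associated macrophage genes 9 of 10 fell (9 adjusted over the list alone; median -3.29, camera adjusted p 3.1e-42). Besides F13a1 these were among others the scavenger receptor genes Cd163 (10.5-fold lower, log2 -3.39, SE 0.38) and Stab1 (4.61-fold lower, log2 -2.21, SE 0.16), and Mrc1, the mannose receptor gene, chosen after its values were seen (5.09 ± 2.21 to 0.257 ± 0.233 CPM). Of 22 genes of disease-associated microglia 8 fell (13 adjusted over the list alone; median -0.68, camera adjusted p 2.1e-14, adjusted p = 0.075 with an estimated correlation), among them Lyz2 (11.6-fold lower), Ch25h (14.9-fold) and Tyrobp, the adaptor of Trem2 (3.99-fold). In phagocytosis and Fc receptors 14 of 20 fell (16 adjusted over the list alone; median -1.91, also with Msr1 at its bound; camera adjusted p 4.2e-42), with Fcgr3 6.09-fold lower and Cybb, the catalytic subunit of the phagocyte oxidase, 15-fold lower. Msr1, a scavenger receptor gene, had 171 counts over the 3AP libraries and 0 over the PLX3AP libraries. That is at least 57.3-fold lower with the 171 taken as exact.

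Complement genes fell in 14 of 15 cases (15 adjusted over the list alone; median -2.29, camera adjusted p 1.4e-54), with C1qa 4.88-fold (51.8 ± 8.03 to 10.6 ± 2.77 CPM) and Itgb2 5.68-fold lower. The type I interferon list fell in 24 of 26 genes, all but Stat2 and Xaf1 (26 adjusted over the list alone; median -1.65, camera adjusted p 1.4e-80). Ifitm3, which blocks viral entry, was 6.22-fold lower and Oasl2 4.35-fold lower. Of 15 antigen presentation genes 7 fell (11 adjusted over the list alone; median -1.08, camera adjusted p 2.5e-21), with B2m 2.16-fold and H2-K1 3.29-fold lower. In the cytokine list 11 of 24 fell (20 adjusted over the list alone; median -1.0, camera adjusted p 4.0e-26). Ccl5 was 96.9-fold lower, on 7 counts over the PLX3AP libraries. Ccl12 was 16.5-fold and Icam1 8.14-fold lower. Il1b had 51 counts in 3AP and 2 in PLX3AP, a ratio of 25.7 with a 95% counting interval of 6.75 to 218. Its adjusted p of 0.014 became 0.051 to 0.086 without 3AP replicates 1 or 2 or PLX3AP replicates 2 or 3. Tnf, with 11 and 0 counts, was not tested, and was at least 3.69-fold lower with the 11 taken as exact. Reactive astrocyte genes fell in 10 of 19 cases (14 adjusted over the list alone; median -1.13, camera adjusted p 8.8e-26, adjusted p = 0.054 with an estimated correlation), with Serpina3n 17.5-fold, Timp1 18.2-fold and Cp 3.75-fold lower. Gfap went from 778 ± 334 to 281 ± 29.8 CPM (edgeR adjusted p 0.037), a call lost without 3AP replicate 2 (0.096), PLX3AP replicate 1 (0.11), PLX3AP replicate 2 (0.14) or PLX3AP replicate 3 (0.11). Csf1 (32.2 ± 3.48 and 24.9 ± 0.866 CPM; adjusted p 0.093, and 0.033 without 3AP replicate 3) and Il34 (8.74 ± 1.20 and 9.97 ± 0.934) did not pass.

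Leukocyte markers fell in 5 of 7 cases (6 adjusted over the list alone; median -3.64, camera adjusted p 6.8e-11). Plac8 was 33.8-fold lower, on only 1, 1 and 2 counts in the PLX3AP libraries. The calls of Ccr2 (without 3AP replicate 1 or PLX3AP replicate 3, adjusted p of 0.071 to 0.082) and Ly6c2 (without 3AP replicate 1 or PLX3AP replicate 2, 0.053 to 0.055) were lost. Endothelial genes fell in 4 of 12 cases and rose in 2 (6 and 2 adjusted over the list alone; median -0.32, camera adjusted p 1.1e-05). Cldn5 was 2.05-fold, Pecam1 2.10-fold and Ly6c1 2.12-fold lower, and Itm2a rose 1.64-fold. Of 10 genes of meningeal fibroblasts 4 fell (5 lower and 2 higher adjusted over the list alone; median -0.48, camera adjusted p 0.0019, adjusted p = 0.37 with an estimated correlation), among them Dcn, 3.06-fold lower, and Col3a1, a fibrillar collagen gene, 1.97-fold lower. The calls of the other 2, Col1a1 and Aldh1a2, were lost without 3AP replicates 1 or 2 or PLX3AP replicate 2, and that of Col1a1 also without PLX3AP replicate 1 (adjusted p of 0.077 to 0.14 and of 0.062 to 0.080).

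The 6 genes that rose with the smallest p were Ltbp4, Cxcl12, Paqr6, Fmo2, Phgdh and Tubb2b. Ltbp4 went from 13.5 ± 1.36 to 33.4 ± 3.00 CPM (log2 1.30, SE 0.11, edgeR adjusted p 4.2e-05). The others were the chemokine gene Cxcl12 (41.0 ± 1.67 to 68.9 ± 5.4), Paqr6 (19.99 ± 1.84 to 37.7 ± 4.79), the monooxygenase gene Fmo2 (1.69 ± 0.289 to 5.95 ± 0.829), Phgdh (55.6 ± 1.68 to 90.3 ± 8.75) and the tubulin gene Tubb2b (87.9 ± 4.95 to 157 ± 23.9). Cholesterol synthesis genes rose in 3 of 15 cases (10 adjusted over the list alone; median 0.26, camera adjusted p 4.7e-09), Cyp51 and Msmo1 among them. The adjusted p of Cyp51, 0.0092, became 0.052 to 0.065 without 3AP replicates 1 or 2. That of Msmo1, 0.014, became 0.066 to 0.094 without 3AP replicates 1 or 2 or PLX3AP replicate 2. The integrated stress response list had 4 of 18 genes higher and 1 lower (5 and 1 adjusted over the list alone; median 0.20, camera adjusted p 0.00059, adjusted p = 0.29 with an estimated correlation). Phgdh and the transporter gene Slc7a5 (79.9 ± 3.99 to 115 ± 15.1 CPM) rose. So did Asns and Psat1, but both lost their call without 3AP replicates 2 or 3 or PLX3AP replicates 2 or 3 (adjusted p of 0.055 to 0.087 and of 0.059 to 0.13). In the myelin list (median 0.16, camera adjusted p 0.0011, adjusted p = 0.46 with an estimated correlation; 0.052 without 3AP replicate 2) Opalin rose 1.94-fold, 1 of 15 genes (2 adjusted over the list alone). Oxidative phosphorylation (0.13, 0.0034, adjusted p = 0.62 with an estimated correlation) lost its call without 3AP replicate 3 (0.072) or PLX3AP replicate 2 (0.11). The granule cell list (0.09, 0.0091, adjusted p = 0.39 with an estimated correlation) lost its call without 3AP replicate 1 (0.15). The erythroid list had a median of 1.26 (camera adjusted p 2.3e-05, adjusted p = 0.26 with an estimated correlation); edgeR called 0 of its 6 genes, 6 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Hopx, an astrocyte marker, rose 1.5-fold. Calb1 (log2 0.00, SE 0.10) and Pcp2 (0.11, SE 0.10) did not pass. No other list passed with all libraries. Without PLX3AP replicate 1 the mitochondrially encoded (0.00027), astrocyte and interneuron lists passed, and without PLX3AP replicate 2 choroid plexus (0.039) and proliferation. Without 3AP replicate 2 the Purkinje cell (0.0052), interneuron and astrocyte lists passed, without 3AP replicate 1 proliferation and astrocytes, and without 3AP replicate 3 proliferation. The adjusted p of these proliferation, astrocyte and interneuron calls was 0.018 to 0.048. The median, mean and test of the precursor, mural, immediate early and NAD lists differed in sign.

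In all, edgeR called 621 genes, 96 higher and 525 lower, with 2-fold or larger changes in 8 and 402. In each of them the groups did not overlap, which held for 16.9% of all tested genes and 10% would show by chance. The count was 401 without 3AP replicate 1, and limma-trend on TPM called 379 or 325. The 96 higher became 47 without 3AP replicate 1, 63 without 3AP replicate 2, 49 without PLX3AP replicate 2 and 54 without PLX3AP replicate 3. They became 144 without PLX3AP replicate 1, 155 with DESeq2, and 53 or 44 with limma-trend on TPM. With the correction for GC content and gene length 818 genes were called, 191 higher and 627 lower. Csf1r lies on chromosome 18 from 61100598 to 61132149, and Ltbp4 on chromosome 7 from 27305136 to 27337692.

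The comparison of PLX3AP with control shows where the mice with both treatments stood against mice given saline. Macrophage genes were lower than in control, oligodendrocyte precursor genes and some chaperones of the endoplasmic reticulum were lower too, and Irf7 was above control. Mrc1 was 17.7-fold lower, at 4.71 ± 0.351 CPM in control and 0.257 ± 0.233 in PLX3AP (log2 -4.15, SE 0.49, n = 3, edgeR adjusted p 0.0056, and 0.064 without PLX3AP replicate 2). Gpr17 was 3.84-fold lower, at 24.4 ± 1.96 and 6.36 ± 1.31 CPM (log2 -1.94, SE 0.18, n = 3, edgeR adjusted p 0.0011). Hspa5, the main chaperone of the endoplasmic reticulum, was at 458 ± 19.6 CPM in control and 251 ± 1.91 in PLX3AP (log2 -0.87, SE 0.07, n = 3, edgeR adjusted p 0.00027).

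Of the 10 border-associated macrophage genes tested 5 were lower (9 adjusted over the list alone; median -3.10, camera adjusted p 2.0e-53). These were Mrc1, Cd163 (10.1-fold lower), F13a1 (9.71-fold), Stab1 (2.93-fold) and Lyve1, whose adjusted p of 0.010 became 0.052 to 0.092 without control replicates 1 or 2 or PLX3AP replicate 2. The homeostatic microglia list had a median of -0.67 (camera adjusted p 2.3e-18, adjusted p = 0.066 with an estimated correlation). None of its 18 genes passed with edgeR over all genes (0; 11 adjusted over the list alone), 12 had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0. Csf1r was at 33.6 ± 1.39 and 18.5 ± 5.92 CPM (log2 -0.86, SE 0.18, adjusted p 0.19), and it was called without PLX3AP replicate 1 (0.049) or PLX3AP replicate 3 (0.0058). P2ry12 was at 9.61 ± 1.68 and 3.81 ± 1.29 CPM (log2 -1.34, SE 0.26). Tmem119 was at 8.38 ± 1.20 and 5.19 ± 1.26 (-0.69, SE 0.20), Cx3cr1 at 12.2 ± 1.03 and 7.84 ± 2.44 (-0.64, SE 0.21). Itgam was at 6.73 ± 1.19 and 4.14 ± 1.29 (-0.70, SE 0.25) and Aif1 at 1.00 ± 0.529 and 0.657 ± 0.204 (-0.60, SE 0.43). The phagocytosis list had a median of -0.48, also with Msr1 at its bound (7 lower and 1 higher adjusted over the list alone, camera adjusted p 5.0e-05, adjusted p = 0.34 with an estimated correlation, and 0.063 without PLX3AP replicate 1). EdgeR called 0 of its 20 genes, 9 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0.

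The type I interferon list stood above control, with a median of 0.58 (camera adjusted p 2.5e-14, adjusted p = 0.053 with an estimated correlation). Irf7 was its 1 called gene of 26 (16 adjusted over the list alone), 1.95-fold higher at 6.03 ± 0.18 CPM (adjusted p 0.043), a call lost without any of control replicates 1, 2 and 3 and PLX3AP replicates 2 and 3 (0.090 to 0.20). Among oligodendrocyte precursor genes 2 of 11 were lower (4 adjusted over the list alone; median -0.37, camera adjusted p 1.6e-13), Gpr17 and the sialidase gene Neu4, whose adjusted p of 0.020 became 0.098 to 0.13 without control replicates 1 or 2 or PLX3AP replicates 2 or 3. Cholesterol synthesis had a median of -0.13 (3 lower adjusted over the list alone, camera adjusted p 0.0030, adjusted p = 0.075 with an estimated correlation). The erythroid list (0.73, 0.00064, adjusted p = 0.37 with an estimated correlation) lost its call without PLX3AP replicate 3 (0.065). The mitochondrially encoded list had a median of -0.31 (camera adjusted p 0.021, adjusted p = 0.64 with an estimated correlation), and the interneuron list 0.08 (0.035, adjusted p = 0.62 with an estimated correlation). For NAD metabolism these values were 0.07 (0.042, adjusted p = 0.15 with an estimated correlation), and for meningeal fibroblasts -0.18 (0.043, adjusted p = 0.58 with an estimated correlation). Hindbrain genes had a median of 0.47 (0.047, adjusted p = 0.26 with an estimated correlation), and stress response genes 0.13 (0.049, adjusted p = 0.58 with an estimated correlation). Each of these 6 lists lost its call in 3 or more of the 6 fits without 1 library, with adjusted p of 0.075 to 0.54. Calls were lost without control replicate 1 (hindbrain and stress response), control replicate 2 (NAD) and control replicate 3 (all but stress response). They were also lost without PLX3AP replicate 1 (meningeal, NAD and hindbrain), PLX3AP replicate 2 (all but NAD) and PLX3AP replicate 3 (all but meningeal). Calb1 (log2 -0.18, SE 0.10), Pcp2 (0.14, SE 0.10), Gfap (0.35, SE 0.29), Csf1 (0.35, SE 0.11) and Il34 (-0.04, SE 0.16) did not pass. No other list passed with all libraries. Complement passed without control replicate 1 or PLX3AP replicate 3 (1.5e-05 to 0.0074), glutamatergic synapse without control replicate 3 or PLX3AP replicate 3 (0.0025 to 0.0060). Choroid plexus passed without control replicate 3 or PLX3AP replicate 2 (0.0064 to 0.025) and oxidative phosphorylation without control replicate 2 or PLX3AP replicate 2 (0.0082 to 0.035). Excitability channels passed without control replicate 1 (0.031), proliferation (0.032) and immediate early genes (0.034) without control replicate 2, and disease-associated microglia without control replicate 3 (0.030). Signs differed between median, mean and test for the mural, cytokine, antigen presentation and reactive astrocyte lists.

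In all, edgeR called 20 genes, 6 higher and 14 lower, and 1556 had an unadjusted p under 0.05. In each of the 20 the groups did not overlap, which held for 14.3% of all tested genes and 10% would show by chance. Cd163, F13a1, Gpr17, Stab1, Tnc (2.01-fold lower), Hspa5 and Manf, a secreted protein of the endoplasmic reticulum (log2 -0.82, SE 0.10, chosen after its value was seen), kept their call whichever library was left out, and the other 13 did not. Among those 13, Etnppl (log2 0.75), Cbx7 (0.43), Galnt6 (0.65), Tprkb (0.39) and Rab37 (0.51) were higher, and Pdia3 (-0.44), Cd48 (-3.26) and Ms4a6d (-2.51), chosen after their values were seen, were lower. They lost their calls without control replicates 1, 2 or 3 or PLX3AP replicates 2 or 3, each gene in 4 or 5 of these fits, with adjusted p of 0.056 to 0.25. The count was 8 without control replicate 1 or control replicate 2, 7 without PLX3AP replicate 2, 13 without PLX3AP replicate 3 and 153 without PLX3AP replicate 1. DESeq2 called 110, edgeR without a filter on low counts 71, limma-trend on TPM 5, and edgeR with a correction for GC content and gene length 45. Mrc1 lies on chromosome 2 from 14229392 to 14332057 and Hspa5 on chromosome 2 from 34771970 to 34777547.

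Genes called in 3AP against control and called in the opposite direction in PLX3AP against 3AP were counted, and are said here to have moved back. The groups are separate samples, so such a gene may never have changed in the PLX3AP mice. Of the 623 genes higher in 3AP than in control, 404 (64.8%) were called lower in PLX3AP than in 3AP and 620 had a fold change of opposite sign, with median log2 fold changes of 1.30 and -1.11. Against control their median in PLX3AP was 0.18. Of the 197 genes lower in 3AP, 67 (34.0%) were called higher in PLX3AP than in 3AP and 185 had the opposite sign, with medians of -0.49 and 0.32, and -0.18 in PLX3AP against control. With the correction for GC content and gene length the 404 became 493 and the 67 became 127. Without 3AP replicate 1 the 197 became 85, the 404 became 244 and the 67 became 31. Without 3AP replicate 2 they became 94, 282 and 38. Without PLX3AP replicate 2 the 404 became 314 and the 67 became 38. With limma-trend on TPM the 404 became 259 or 203, and the 67 became 28 or 25. Irf7, Lcn2, C1qa, B2m and Icam1 are among the 404, and Ltbp4, Opalin, Hopx and Phgdh among the 67. Hspa5 was called lower in both comparisons (log2 -0.50, SE 0.07, in 3AP against control and -0.36, SE 0.07, in PLX3AP against 3AP), the 1 gene to do so. The 471 genes called in opposite directions compare with 19.7 and 1.14 expected if the up-then-down and down-then-up lists overlapped at random. In 20 simulations of unchanged groups 0.05 genes were so called on average (1 at most). Those simulations called almost no genes at all, on average 0.35 higher and 0.55 lower in 3AP against control. Their overlap was therefore nearly fixed beforehand, and does not gauge how much of the 471 comes from the shared 3AP libraries. Over all genes the covariance of both sets of fold changes was -0.23, against -0.042 on average in the simulations, which share the 3AP libraries in the same way. The simulations drew each gene on its own, without the trends with GC content and gene length that differed between libraries. Their covariances and correlations are therefore not a matched level for unchanged groups. Both comparisons use the 3AP libraries, so part of the excess, and of the 620 and 185 opposite signs, may come from them. In the simulations of unchanged groups the fold changes correlated at -0.50 on average across genes, against -0.77 observed. The 3 libraries cannot be divided so that each comparison has 2 of its own. Without 3AP replicate 1 the count was 275, and limma-trend on TPM gave 287 or 228.

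Called against control in both 3AP and PLX3AP were 10 genes with the same direction. They included Irf7, Etnppl, Cbx7, Galnt6 and Tprkb, which were higher, and Gpr17, Tnc, Manf and Hspa5, which were lower. Of these, Gpr17, Tnc, Hspa5 and Manf kept both calls whichever library was left out. Random overlap would give 0.225 higher and 0.166 lower. Simulations of unchanged groups sharing the control libraries gave 0.2 on average, but called only 0.35 genes higher and 0.55 lower in 3AP against control. That overlap too was nearly fixed beforehand, and sets no level for genes called against shared controls. The covariance was 0.060 against 0.043 on average in those simulations (0.052 at most), a difference of 0.017. Since those simulations lacked the library trends with GC content and gene length, no conclusion is drawn from this difference. The correlation of the same fold changes, across genes that are not independent replicates, was 0.30, below that of every simulation (0.45 to 0.55). F13a1, Stab1 and Ms4a6d were called higher in 3AP and lower in PLX3AP than in control, but Stab1 lost the 3AP call without control replicates 1 or 2 or 3AP replicates 1 or 2 (adjusted p of 0.088 to 0.11). Ms4a6d, chosen after its values were seen, lost the PLX3AP call without control replicates 1, 2 or 3 or PLX3AP replicates 2 or 3 (0.071 to 0.22).

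**Figure D3:**
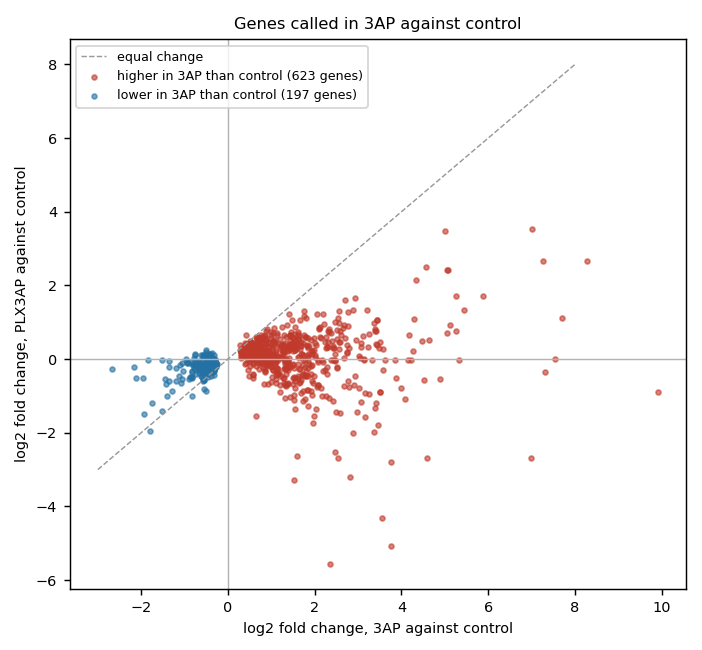
Log2 fold change of the 820 genes called in 3AP against control (x axis) and in PLX3AP against control (y axis), 1 point per gene, 3 libraries per group. The 623 genes higher in 3AP have a median of 1.30 on the x axis and 0.18 on the y axis.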

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

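Tests chosen only after the result was seen are those on meningeal tissue, on the number of microglia and on leukocytes, and the corrections for Ttr and for GC content and gene length. The test of further endoplasmic reticulum genes, given under other observations, was prompted by genes already called in these libraries.

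Rows of the count files without a gene name were used in no comparison, and tested beside the named genes with edgeR 9 of 257 were higher in 3AP than in control, 9 lower in PLX3AP than in 3AP and 1 lower in PLX3AP than in control. Of the 16634 named genes 623, 525 and 14 were called in these directions in the main fit. In the first 2 comparisons that is about the same share.

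Border-associated macrophage genes were lower in PLX3AP than in control, with a list median of -3.10. A smaller share of meninges in the PLX3AP dissections, where these cells also live, would lower meningeal fibroblast genes as far, but their median was -0.18 and the difference between both medians was -2.92 (permutation over genes, p = 0.00079). In the fit with Ttr as a covariate the macrophage median was -3.10 as before. That fit could hardly give another value, because Ttr did not separate the groups. It was at 94.3, 309 and 3813 CPM in the control libraries and at 1917, 11.5 and 1751 in the PLX3AP libraries. Ttr was thus not lower throughout PLX3AP, as a smaller share of choroid plexus in those dissections would make it. The loss of macrophages that depend on the CSF1 receptor remains as a hypothesis found on the same data, and no test here measured cell number. A group with PLX3397 alone, which would show these genes without 3-AP, was not analysed here.

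Interferon genes were higher in 3AP than in control, with a list median of 2.35. More microglia, each with an unchanged level, would raise microglial and interferon genes alike, but the homeostatic microglia median was 0.78 and the difference 1.57 (permutation over genes, p = 2.0e-05). Microglia that lower those markers as they respond leave this less certain, since P2ry12 did not rise with Cx3cr1 and Itgam. Leukocytes entering the tissue cannot be told apart from a response of resident cells, because the blood leukocyte median rose too, to 2.67. Of its 18 genes 7 had enough counts to test, and the most abundant, S100a9, was at 6.71 ± 3.21 CPM in 3AP.

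Splits of the 6 libraries of a comparison into other groups of 3 number 10 with the real split, too few for a share under 0.05. In 3AP against control the real split called 820 genes and the highest other 0 (1 of 10 splits as large), and in PLX3AP against 3AP 621 and 118 (1 of 10). In PLX3AP against control the real split called 20 and another 128 (2 of 10), several times as many, which points to a structure of the samples: it sets control replicates 1 and 2 and PLX3AP replicate 1 against the other 3. GC content and gene length are candidate explanations that were not separated. Log2 CPM fell with GC content across genes in those 3 libraries (Spearman rho -0.27, -0.14 and -0.61, relative to the mean of all libraries) and rose in the other 3 (0.30, 0.42 and 0.45). With gene length it rose in those 3 (0.32, 0.43 and 0.18) and in the others gave -0.54, -0.37 and 0.12. With offsets for both at once that split called 0 genes and the real one 45. The split with 118 genes in PLX3AP against 3AP set 3AP replicates 1 and 3 and PLX3AP replicate 1 against the other 3 libraries. Spearman rho with GC content was 0.15, -0.48 and -0.61 in those libraries and 0.44, 0.42 and 0.45 in the others. It was not refitted with offsets, so a structure of the samples is not excluded in that comparison. No biological explanation was tested, and library batches are not given in the sources used here.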

How the results depend on the processing

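The Ttr covariate and the GC and length correction were chosen after seeing the data; all other settings were planned. An absolute log2 fold change of 1 or more, which keeps part of the calls by construction, gave 403 genes in 3AP against control, 410 in PLX3AP against 3AP, 10 in PLX3AP against control and 303 moved back. TPM with limma-trend, with 1 or 0.1 added, gave 482 or 416, 379 or 325, 5 or 5, and 287 or 228; the cause was not tested. GC and length correction gave 1320 genes in 3AP against control (795 of them among the 820) and 45 in PLX3AP against control. In the latter, DESeq2 gave 110, no filter 71, the Ttr covariate 12 and a block by replicate number 10, and the cause was not tested. That block has no ground in the data. Libraries of the same number correlated at -0.20 to 0.093 over 9 pairs once group means were removed. Of the 9 libraries 0 were closest to their own number in both other groups at once, though some were in a single group. Leaving out 1 library, which also leaves fewer samples, gave 466 to 798 genes in 3AP against control, 401 to 715 in PLX3AP against 3AP, 7 to 153 in PLX3AP against control and 275 to 483 moved back. It gave 45 to 52 of 96 list tests passed, an interferon median of 2.23 to 2.40 in 3AP against control and a homeostatic microglia median of -1.69 to -1.37 in PLX3AP against 3AP. With an estimated correlation 20 list tests passed in place of 48. The choroid plexus list, not called with all libraries in PLX3AP against control, turned and passed without control replicate 3 (1.85) and without PLX3AP replicate 2 (0.38), over a range of -0.66 to 1.85. Counting each gene once per comparison, 138 of 198 called results kept direction and call under every setting run and 60 did not. Counting each list once per comparison, 18 of 46 did. This leaves out 2 of the 48, interferon in 3AP against control and homeostatic microglia in PLX3AP against 3AP, which kept theirs throughout. No called gene turned direction. RLE scaling and no TMM moved the median of all genes by under 0.1. Depth limits genes such as Tnf and Il1b, with 0 to 51 counts over a group.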

Other observations

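The GC and length correction was chosen only after results were seen, and the genes named in the next 2 paragraphs were chosen after their values were seen.

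Single genes outside the lists were also among those called. Saa3, a serum amyloid A gene induced in inflamed tissue, was at 0.0652 CPM on average in control and 70.3 in 3AP (log2 9.92, SE 0.79, n = 3, edgeR adjusted p 0.00041). That fold rests on 4 counts over the control libraries. Saa3 had 4314 counts in 3AP against 2 in PLX3AP, a ratio of 2170 (95% counting interval 600.3 to 17923). Lrg1, a secreted glycoprotein of activated endothelium, rose by a log2 of 3.33 (SE 0.32) after 3-AP and was lower by a similar amount in PLX3AP than in 3AP (-3.35, SE 0.32). Selp, which encodes P-selectin, had 0 counts in control and 117 in 3AP, at least 39.2-fold higher with the 117 taken as exact. Mmp3, a matrix metalloproteinase gene, had 2 and 305 counts, a ratio of 153 (42.1 to 1271).

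Fads2 and Fads1 encode fatty acid desaturases. Fads2 fell by 0.73 on the log2 scale (SE 0.08, n = 3, edgeR adjusted p 0.00022) in 3AP and rose by 0.65 (SE 0.08) in PLX3AP against 3AP, and Fads1 fell by 0.46 and rose by 0.42. Gkn3, an endothelial gene, fell by 2.67 (SE 0.32) and rose by 2.41 (SE 0.32). Fabp7, a fatty acid binding protein of Bergmann glia and precursors, fell by 1.52 (SE 0.22) in 3AP and did not pass in PLX3AP against control (-1.40, SE 0.22, edgeR adjusted p 0.070, and 0.022 without PLX3AP replicate 1).

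Hspa5, Manf and Pdia3, all of protein folding in the endoplasmic reticulum, were lower in PLX3AP than in control. This prompted a test of a wider fall on 15 further genes, a list not among the 32 fixed beforehand. The test used the same libraries and is not independent support, and its p-values are not adjusted. The median log2 fold change of the 15 genes was -0.11, 11 of 15 were lower, and camera gave p = 6.0e-05 (0.035 with an estimated correlation, and 2.7e-05 with GC and length correction, where the median was -0.04). EdgeR called 0 of the 15, 5 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. The small median is consistent with a wider but slight fall, far from that of Hspa5 (-0.87). For the same genes the camera test of limma gave 0.26 in 3AP against control and 0.071 in PLX3AP against 3AP. With GC and length correction camera gave 0.46 and 0.026. Without it camera with an estimated correlation gave 0.47 and 0.27, and fry 0.36 and 0.038, so in PLX3AP against 3AP the result depends on the test. In PLX3AP against control fry gave 0.011.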
